A study of Drosophila melanogaster with 12 samples.

How the data were processed

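RNA of sieved heads of frozen y w flies was labelled with biotin and hybridized to 1 Affymetrix Drosophila array per time point, with about 100 to 200 heads per sample, per the labels' protocols. The authors' deposited values are log2 expression values, 1 per probe set, made with RMA, per the submitters' processing notes. The RMA version, the set of arrays normalized together, and any filter are not given in the sources used here. The array medians lay between 4.926 and 4.958, so the deposited values were used without further normalization in the main analysis. RMA forces the arrays to a common distribution, so a change shared by most transcripts would not show.

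Arrays were assigned to the LD group (6) or the DD group (6) and to a clock time from their titles. Arrays were numbered by clock time within each group, so the same number in LD and DD is the same clock time on different days. The fits model clock time with a cosine and sine, and a fit with clock time as a block was an alternative. Probe sets were named through the platform annotation and a RefSeq gene table. Of 14010 probe sets, 12442 had 1 gene, 327 had several and 1197 had none, and 12393 of those with 1 gene matched a RefSeq gene. The 44 control probe sets were left out of the tests, which left 13966. Probe sets with several genes or none were tested but not named. A gene with several probe sets was represented by the one of highest mean over all arrays, which gave 10843 genes.

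All tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. The rhythm test was a moderated F test of the cosine and sine of clock time with a period of 24 h, with regime as a covariate. It left 8 residual degrees of freedom; the written design stated a wrong number there, and the model itself was fitted as written. The DD minus LD difference came from the same fit. The light test was an indicator for ZT4, ZT8 and ZT12 with regime and a 6-level clock time factor (4 residual degrees of freedom). The test of rhythm differences was an F test of the regime by cosine and regime by sine terms (6 residual degrees of freedom). Amplitude is the fitted distance from mean to peak in log2, and standard errors of amplitude and peak time came from the delta method. A p-value from these fits measures the scatter of single arrays around the model. Clock time was confounded with the session of collection.

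The models, the 22 gene lists and the rule for naming genes were fixed before the data were examined. The lists were core clock, reported clock outputs, phototransduction, photoreceptor transmitter handling, activity-regulated, heat shock, immunity, xenobiotic detoxification, antioxidant defence, carbohydrate and lipid metabolism, neuropeptides, fat body and sex-biased head fat body, testis and male accessory gland, ovary and eggshell, midgut, thoracic muscle, neuronal, glial, ribosomal proteins, proteasome, mitochondrial respiration, and odorant-binding and olfactory genes. After the data were seen, 2 entries whose names had matched a wrong gene were corrected, 1 by pointing it to its gene and 1 by leaving it out. Of 564 measured list genes, 23 are in more than 1 list; none of the male reproductive tract, ovary or thoracic muscle markers is in another list, and 3 of the midgut markers are. Shifts of lists were tested with camera, with the preset correlation between genes of 0.01 and again with an estimated one. Rhythmicity of lists was tested with Fisher's exact test, two-sided. List members without a tested probe set of their own were not analysed here. How many marker genes heads themselves express was not analysed here, and heads hold muscle too.

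For rhythm the naming rule takes every measured core clock gene and the 20 genes of largest amplitude among those past the threshold whose LD and DD peaks lay within 4 h. For DD minus LD and for light it takes the 12 largest rises and 12 largest falls past the threshold with the same sign at all clock times concerned. For rhythm differences it takes the 12 with the smallest p past the threshold. Where fewer than 5 passed, the 10 with the smallest p were named and said not to pass. List examples are taken from the 4 members with the smallest p. Genes named for marker levels per array (betaTry, Jon99Fi, Acp95EF, Act88F and Cp15) were chosen after their values were seen, as were the other probe sets of tim.

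The fits were tested on simulated data with independent noise per array and 200 changed probe sets among 13966. For changes of 1 and 2 (log2; peak to trough for rhythms), the rhythm test recovered 79.5% and 91.0%, the DD minus LD test 96.0% and 98.5%, the light test 52.0% and 89.0%, and the rhythm difference test 0% and 72.0%. Real arrays share disturbances between genes, which the simulation does not hold. With fewer than 200 changed probe sets the adjusted threshold is stricter, so these shares may be too high for the data. In the data tim, at 4.70-fold peak to trough, had an adjusted p of 0.204 in the limma rhythm test over all probe sets.

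Alternatives chosen with the design were a filter on the mean, median centring, a second quantile normalization, a variance trend, a threshold of 0.01, leaving out each array, and other forms of each model, among them a permutation test of 24-h Fourier power with 10000 random orders. Alternatives added after the data were seen leave out ZT4 and CT12 (and CT4), weight arrays by quality, add the control transcript difference or a body marker score as a covariate, test lists at an unadjusted p, or normalize the values of the list tests again. The body score is the mean of the midgut, male reproductive tract and thoracic muscle scores. In exploration the score had been pooled over genes, which gave a different count, so both definitions and the 3 single scores are reported. A later test of gradual change fitted a steady trend over the hours of both days beside regime, with and without the cosine and sine. The estimation of array weights for the rhythm difference test stopped before full convergence.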

Results

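Heads of adult Drosophila melanogaster carrying the body colour and eye colour mutations yellow and white (y w) were profiled over 2 days. Flies entrained to 12 h of light and 12 h of dark were collected every 4 h during a further light/dark day (LD) and then during a day of constant darkness (DD). LD times are written as Zeitgeber time (ZT) and DD times as circadian time (CT), each counted from actual or subjective lights-on. Each day gave 6 arrays, at 4, 8, 12, 16, 20 and 24 h, and no time point was repeated. The error of every estimate is therefore the scatter of the 12 arrays around the fitted model, and it does not separate fly-to-fly from technical variation. The number of arrays limits the precision. Of 14010 probe sets on the array, 13966 were tested and 44 were control probe sets. Pairwise correlations between arrays ranged from 0.956 to 0.995, and no pair held identical values.

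The arrays differed in the 3' to 5' signal of control transcripts and in marker transcripts of midgut, male reproductive tract and muscle. The signal of the 3' probe set minus that of the 5' probe set, averaged over the actin, GAPDH and eIF-4a control transcripts, was 3.12 (log2) at ZT4 and 3.46 at CT12. It was 2.64 at CT4 and lay between 1.69 and 2.20 in the other 9 arrays. Digestive enzyme genes of the midgut varied widely. The trypsin gene betaTry was 10.74 (log2) at ZT12 and 7.11 at ZT16. The serine protease gene Jon99Fi was 8.68 at CT12 and 2.40 at CT20, near the lowest value of that array (2.08). The male accessory gland gene Acp95EF ranged 43.8-fold, and the flight muscle actin gene Act88F ranged 60.2-fold, both with their highest value at CT12; signal over background was not measured, so the low ends of these ranges are uncertain. The score of the 34 measured midgut markers was 1.04 at ZT12 and 1.02 at CT12. It lay between -0.741 and -0.721 at 16 and 20 h of both days. The 23 ovary and eggshell markers varied less, over a range of 0.318, with 1 array apart. The chorion gene Cp15 reached 9.76 at ZT12 against 5.71 to 6.03 in the other 11 arrays.

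**Figure D1:**
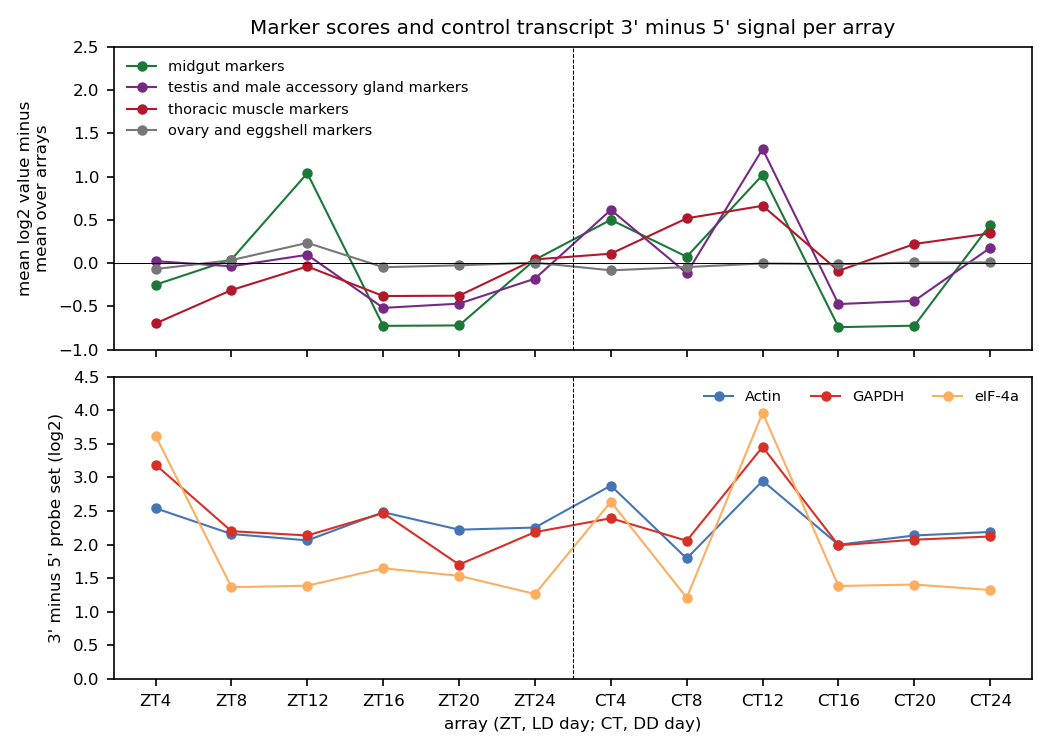
Marker scores (upper panel, mean log2 value of a list's members minus its mean over arrays) and the log2 difference between 3' and 5' probe sets of 3 control transcripts (lower panel), for each of the 12 arrays; the dashed line parts the LD and DD days. Midgut scores peak at ZT12 (1.04) and CT12 (1.02), and the eIF-4a difference is highest at CT12 (3.96) and ZT4 (3.62).

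The first comparison asked which transcripts followed a 24-h rhythm over both days. Among core clock genes, timeless (tim), which encodes the partner of PERIOD, had an amplitude of 1.12 ± 0.147 (log2, SE), a 4.70-fold peak-to-trough ratio, and peaked at 16.2 ± 0.503 h. The transcription factor gene vrille (vri) had a peak-to-trough ratio of 3.23 and peaked at 12.9 ± 0.541 h. The ubiquitin protease gene Usp8 had a ratio of 4.27 and peaked at 13.9 ± 0.653 h. The F-box protein gene slmb and period (per) had smaller ratios of 1.53 and 1.39, with peaks at 16.6 and 14.5 h. These 5 of the 16 measured core clock genes were rhythmic when adjusted over the list alone, with limma adjusted p of 0.000675 for tim and vri, 0.00229 for Usp8, 0.00566 for slmb and 0.0132 for per. In DD the CT12 value of per, 6.1, lay above the others (5.6 to 5.72), and per did not pass without ZT16 (adjusted p over the list alone 0.0561), without ZT4 and CT12 (0.0638) or in the DD day alone (0.249). None passed when adjusted over all probe sets, where tim had an adjusted p of 0.204 and vri of 0.294.

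Clk, which encodes the activator of per and tim transcription, reached its fitted peak at 3.57 ± 1.22 h, in the morning, with a ratio of 1.73 and an adjusted p over the list alone of 0.081. The chromatin remodeller gene kis had a ratio of 1.17 and an adjusted p over the list alone of 0.101. For the other 9 members (dco, cwo, Pdfr, cyc, cry, tws, Pdp1, Pdf and jet) the adjusted p over the list alone was 0.425 or higher, and their ratios lay between 1.02 and 1.39. Of these, cry had a fitted amplitude of 0.17 ± 0.146, and the neuropeptide gene Pdf of 0.0185 ± 0.0534. In DD the CT12 value of cry, 7.16, lay below the others (7.81 to 8.17). The limma adjusted p of cry over the list alone was 0.0615 without ZT4 and CT12 and 0.0293 also without CT4. With the control transcript difference as a covariate it was 0.0429. These last 2 of 28 settings, chosen after the data were seen, were the only ones that cry passed. In the LD day alone, 4 core clock genes (tim, vri, Usp8 and per) passed over the list alone, and in the DD day alone 3 (tim, vri and slmb) did. The limma adjusted p over the list alone was 0.124 for slmb in the LD day alone. For Usp8 in the DD day alone it was 0.0755. The mean of slmb over all arrays, 4.11 (log2), lay below the array medians, so its signal was low. Another probe set of tim gave an amplitude of 0.796 ± 0.12 and a peak at 16.1 h, and the third, with low signal, gave 0.0507 ± 0.0396.

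Across all 13966 probe sets, 1 had a limma adjusted p under 0.05. It measured Culd, which encodes a CUB and LDLa domain protein, with an amplitude of 0.602 ± 0.0563 and a peak at 1.57 ± 0.357 h (adjusted p 0.0228). Culd was highest at CT4 (8.55) and lowest at ZT12 (7.26). The other genes among the 10 with the smallest p did not pass. After Culd came CG10433, with an amplitude of 0.388 and a peak at 0.371 h, and then tim, vri, Nagk, CG42269, Usp8, CG1441, CG13305 and Dip-B. Nagk, CG13305 and Dip-B had fitted peaks at 1.92, 1.60 and 2.85 h and CG1441 at 22.1 h. At an unadjusted p under 0.05 there were 466 probe sets, against 698 expected by chance. Culd did not pass when any of 10 of the 12 arrays was left out, all but CT8 and CT16, and the count was then 0.

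**Figure D2:**
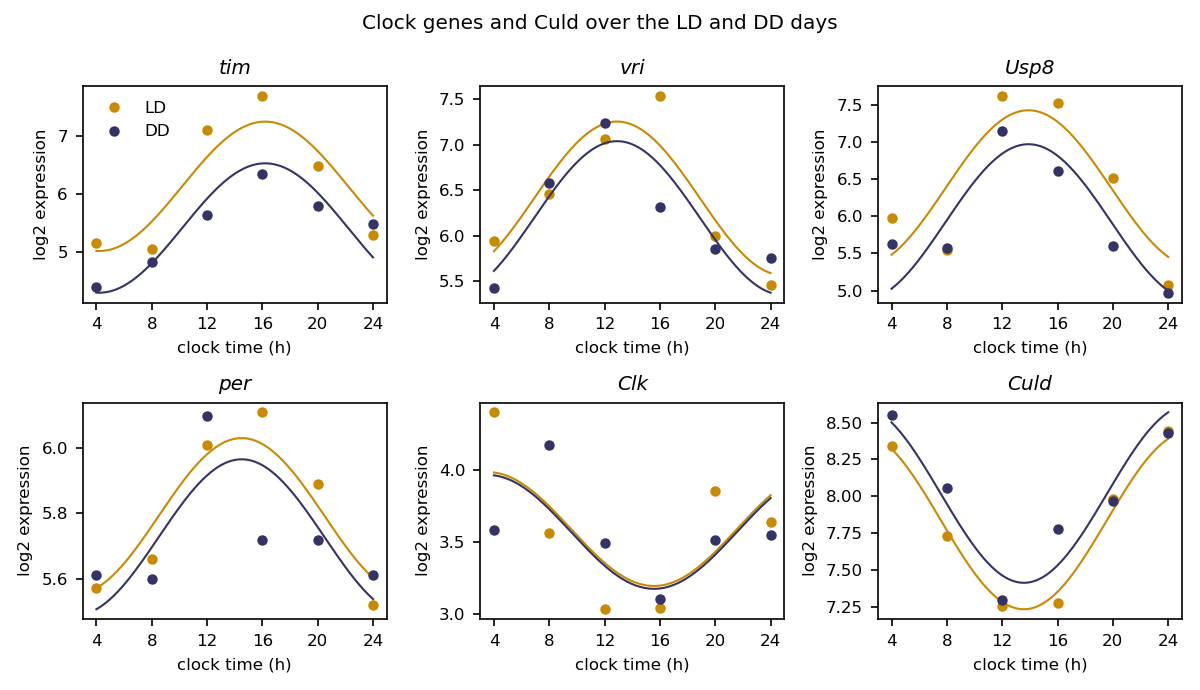
Log2 expression against clock time for 5 core clock genes and Culd; points are single arrays (LD and DD) and lines the 24-h cosine fitted to both days with a separate mean for each. The fitted peaks of tim, vri, Usp8 and per lie between 12.9 and 16.2 h, and those of Clk and Culd at 3.57 and 1.57 h.

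No gene list was enriched among genes past the threshold, since 1 gene passed; Fisher's exact test, two-sided, gave an adjusted p of 1 for all 22 lists. At an unadjusted p under 0.05, a setting chosen after the data were seen, 7 of 16 core clock genes (43.8%) passed against 3.33% of other genes (adjusted p 9.46e-06). The same held for 7 of 29 genes of a list of reported clock outputs (24.1%; adjusted p 0.000441). That list was drawn up from general knowledge of head transcripts reported to cycle, and some reports may rest on related samples, so it is not independent evidence. Adjusted over the list alone, 2 of its members passed, and 0 members did in each of the other 20 lists. Its examples were CG9649, with an amplitude of 0.329 and a peak at 4.18 h, Achl, with 0.754 and 20.9 h, CG2121, with 0.465 and 11.9 h, and the glucuronosyltransferase gene Ugt35B1, with 0.947 and 4.28 h. In the other 20 lists, between 0 and 4 members had an unadjusted p under 0.05. Carbohydrate and lipid metabolism had 4 of 35, among them the maltase genes Mal-A1 and Mal-A6, with an adjusted p of 0.219.

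The second comparison asked which transcripts differed in level between the days. Among the genes that rose in DD, the adult cuticle protein gene Acp1 was 11.47 ± 0.45 (log2, SD, n = 6) in DD and 9.52 ± 0.355 (n = 6) in LD, a 3.87-fold difference. Gasp, which encodes a chitin-binding protein, was 2.05-fold higher. CG7214, CG8736, CG4000, CG7203 and CG11413 were higher by 3.59-fold, 3.56-fold, 3.03-fold, 2.87-fold and 1.48-fold. In DD, 4 genes fell. CG34166 was 4.39-fold higher in LD, and Gnmt, which encodes glycine N-methyltransferase, was 3.18-fold higher in LD. Listericin, an antibacterial peptide gene, was 1.81-fold higher in LD, and CG4572 was 1.41-fold higher in LD. Each of these 11 genes differed in the same direction at all 6 clock times. The DD values were not level. At CT24 Acp1, CG7214, CG4000, CG7203, Gasp, CG11413 and Listericin had the DD value nearest to LD. For Acp1 it was 10.63, against 11.50 to 11.99 at the other DD times. In CG8736, CG34166, Gnmt and CG4572 another DD array lay nearest to LD.

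**Figure D3:**
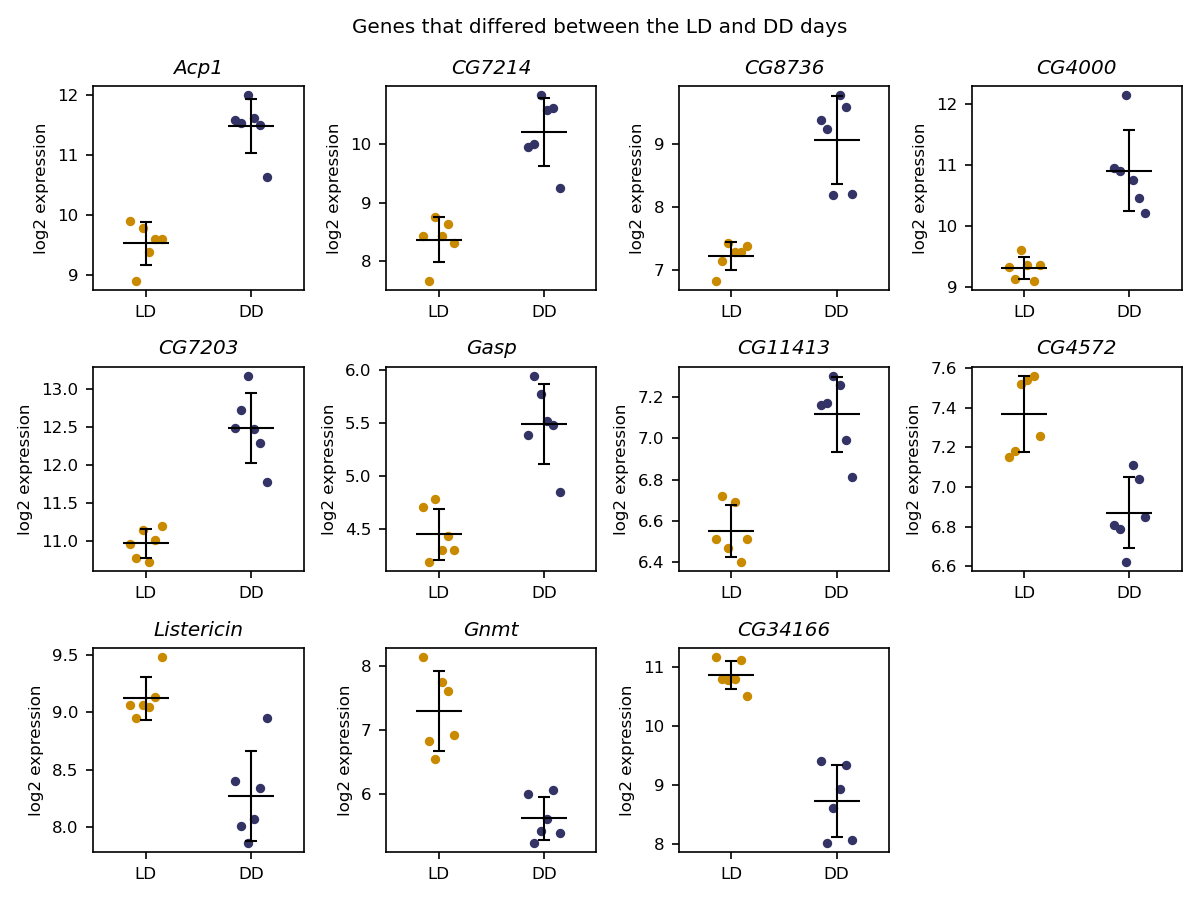
Log2 expression of the 11 named genes that differed between days; points are single arrays, horizontal bars the mean and whiskers the SD of 6 arrays. For example, the 6 DD values of Acp1 lie between 10.63 and 11.99 and its 6 LD values between 8.89 and 9.89.

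With a 12th probe set that has no gene name here (2.44-fold higher in DD), 12 probe sets had a limma adjusted p under 0.05, 8 higher and 4 lower in DD. The adjusted p was 0.0109 for Acp1, CG7214, CG7203, CG34166 and the unnamed probe set, and between 0.0135 and 0.0426 for the other 7. At an unadjusted p under 0.05 there were 616 probe sets, against 698 expected by chance. With body tissue marker scores as covariates, chosen after the data were seen, 11 probe sets passed with the midgut score, 10 with the male reproductive tract score, 10 with the body markers pooled, 0 with the muscle score and 0 with the mean of the 3 scores. With that mean CG34166 differed by -2.03 ± 0.296 (log2, SE) in place of -2.13 ± 0.252, with an adjusted p of 0.0694, and Gasp by 1.06 ± 0.176 in place of 1.04 ± 0.146, with an adjusted p of 0.147. With clock time as a block in place of the cosine and sine, 11 probe sets passed, 8 of them among these 12. The count was 1 without CT4, 4 without CT20, 5 without each of ZT16, CT8 and CT16, 6 without ZT20, 7 without ZT12 and 22 without CT24. With a steady trend over the hours fitted beside regime, also chosen after the data were seen, 0 probe sets passed, with standard errors 3.19-fold as large. The regime step of Acp1 was then 2.94 ± 0.662 (log2, SE), that of CG34166 0.035 ± 0.476 and that of Gnmt 0.63 ± 0.396. For the last 2 this depended on the cosine and sine, since without them the step was 0.813 ± 0.225 and 0.849 ± 0.316 of the difference between days, and from ZT24 to CT4 it was 0.514 and 0.546. All LD values of CG34166 lay between 10.52 and 11.17 and all DD values between 8.02 and 9.42. The DD day always followed the LD day, so darkness could not be told apart from any other change at that step.

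Genes of mitochondrial respiration were higher in DD as a group. Of 73 measured members, 67 had a positive difference, with a median of 0.196 (log2; camera adjusted p 1.43e-15). Most members were taken by gene name prefix, which brought in like-named genes such as ATPsynbetaL and SdhAL. Which members heads express, and whether male reproductive tract tissue adds to this shift, was not analysed here. The complex I subunit genes ND-B14 and ND-B22 differed by 0.335 and 0.233, and the ATP synthase subunit genes ATPsyndelta and ATPsynB by 0.263 and 0.523. None passed alone. Genes of carbohydrate and lipid metabolism were lower in DD as a group, with 26 of 35 negative and a median of -0.0957 (adjusted p 0.000271). The acetyl-CoA synthetase gene AcCoAS differed by -0.497 and the perilipin gene Lsd-1 by -0.483. Adjusted over the list alone, 2 members fell. These were the 2 lists that held with an estimated correlation between genes, both at an adjusted p of 0.0347. With the thoracic muscle score as a covariate the mitochondrial median was 0.086 (camera p 0.0702 with an estimated correlation). Thoracic muscle markers moved with the same days: 19 of 20 were higher in DD, with a median of 0.609 (adjusted p 2.09e-09, and adjusted p 0.121 with an estimated correlation). Without ZT4 and CT12, chosen after the data were seen, the muscle median was 0.362 (adjusted p 2e-09), the mitochondrial median 0.183 and the metabolic median -0.0946. The myosin light chain genes Mlc1 and Mlc2 differed by 0.941 and 0.744. Adjusted over the list alone, 2 members rose.

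Another 5 lists passed with the preset correlation only. The 16 core clock genes had a median of -0.0715 (adjusted p 0.0195, and adjusted p 0.188 with an estimated correlation), with tim at -0.722 ± 0.208. Heat shock genes had 8 of 10 negative and a median of -0.183 (adjusted p 0.0021, and adjusted p 0.188 with an estimated correlation). Their score was lowest at CT4 (-0.358), CT12 (-0.169) and ZT4 (-0.162), the arrays with the highest 3' minus 5' control signal. Without ZT4 and CT12 the median was -0.175 (camera adjusted p 0.000436). The heat shock factor gene Hsf, at -0.27, fell when adjusted over the list alone. Fat body and sex-biased head fat body genes had 12 of 14 negative and a median of -0.228 (adjusted p 0.00256, and adjusted p 0.233 with an estimated correlation); without ZT4 and CT12 the median was -0.133 (adjusted p 0.00389). Adjusted over the list alone, the odorant-binding protein gene Obp99b (-1.23 ± 0.214; adjusted p 0.0848 over all probe sets) fell and Obp44a (0.309) rose. Antioxidant genes had a median of -0.0743 (adjusted p 0.0488, and adjusted p 0.598 with an estimated correlation), which did not pass when arrays were centred on their medians (adjusted p 0.0515). Their score was lowest at ZT4 and CT12, the arrays with the highest 3' minus 5' control signal, and without these arrays the median was -0.0399 and did not pass (adjusted p 0.314). The methionine sulfoxide reductase gene MsrA fell when adjusted over the list alone (-0.906 ± 0.156; adjusted p 0.0848 over all probe sets). All 25 testis and male accessory gland markers were higher in DD, with a median of 0.189 (adjusted p 5.41e-06, and adjusted p 0.527 with an estimated correlation). These markers reached their highest score at CT12. Without ZT4 and CT12 their median was 0.0373 and did not pass (adjusted p 0.206). The yolk protein genes Yp1, Yp2 and Yp3 of the fat body list were lowest at CT12 (12.54, 11.86 and 12.51). Whether the share of males differed between samples was not analysed here, so the shifts of these 2 lists do not separate sex from regime.

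The other 14 lists did not pass. Their medians were 0.189 for midgut markers, 0.0711 for glial markers, 0.0582 for xenobiotic detoxification, 0.0552 for photoreceptor transmitter handling, 0.0507 for phototransduction, 0.036 for reported clock outputs and 0.00483 for odorant-binding and olfactory genes. They were -0.00883 for neuropeptides, -0.0213 for activity-regulated genes, -0.0255 for ovary and eggshell markers, -0.034 for neuronal markers, -0.0407 for proteasome genes, -0.0437 for immunity genes and -0.0953 for ribosomal protein genes, which passed after a further quantile normalization (adjusted p 0.0118). The median of odorant-binding genes was then -0.0153, of the opposite sign. Without ZT4 and CT12 the medians of midgut markers (-0.107) and of odorant-binding genes (-0.0171) had the opposite sign. Xenobiotic detoxification (0.104, adjusted p 0.00879) and glial markers (0.0951, adjusted p 0.0062) then passed with the preset correlation. No value with an estimated correlation is given without these arrays. The antibacterial peptide gene DptB, at -0.475, fell when adjusted over its list alone. For neuropeptides and neuronal markers the mean was positive, at 0.0264 and 0.00162, and for odorant-binding genes negative, at -0.0183. Nplp3, a neuropeptide-like precursor gene, differed by 0.796 ± 0.164 and was higher in DD at all 6 clock times. It rose when adjusted over the list alone and did not pass over all probe sets (adjusted p 0.216).

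The third comparison asked whether light itself shifted transcripts, by setting LD minus DD at 4, 8 and 12 h against LD minus DD at 16, 20 and 24 h. No probe set passed in limma, the smallest adjusted p was 0.844, and 535 probe sets had an unadjusted p under 0.05, against 698 expected by chance. The 10 genes with the smallest p did not pass. They were the muscle actin gene Act88F (-2.28 ± 0.281, log2, SE), the cytochrome P450 gene Cyp28d1 (-0.912 ± 0.122), the male ejaculatory bulb protein gene Ebp (-1.68 ± 0.256), the polyubiquitin gene Ubi-p63E (-1.51 ± 0.251), CG3348 (1.08 ± 0.19), Gk1, CG7997, CG46339, Acsx3 and TRAM.

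Genes of xenobiotic detoxification had a negative light effect as a group. Of 44 members 31 were negative, with a median of -0.133 (camera adjusted p 0.000356, and adjusted p 0.469 with an estimated correlation). This contrast of both days is not a level in light. From 4 to 24 h the list score was 0.141, -0.231, -0.198, -0.00203, 0.188 and -0.123 in LD. In DD it was 0.246, 0.0794, -0.027, 0.127, 0.0239 and -0.224. Cyp6d5 and GstE3 had light effects of -1.19 and -0.587, and 1 member, Cyp28d1, passed with a negative effect when adjusted over the list alone. Testis and male accessory gland markers had a median of -0.246 (adjusted p 0.00115, and adjusted p 0.841 with an estimated correlation). The other 20 lists did not pass. The outcome depended on ZT4 and CT12. Without them the male markers had a median of 0.222, of the opposite sign, and passed (adjusted p 0.0414), and xenobiotic detoxification had -0.28 (adjusted p 0.000388). Glial markers (-0.293, adjusted p 0.000147), muscle markers (-0.283, adjusted p 0.0111) and ribosomal protein genes (0.173, adjusted p 0.0187) then passed too. These calls rest on the preset correlation, and no value with an estimated one is given without ZT4 and CT12.

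The fourth comparison asked whether rhythms differed between LD and DD. No probe set passed in limma, the smallest adjusted p was 0.858, and 493 had an unadjusted p under 0.05. The amplitude of tim was 1.40 ± 0.171 in LD and 0.87 ± 0.171 in DD (unadjusted p of the difference 0.0694, adjusted over the list alone 0.599). For vri it was 0.938 ± 0.174 and 0.771 ± 0.174, and for per 0.31 ± 0.0767 and 0.177 ± 0.0767. The second probe set of tim gave 1.05 ± 0.125 and 0.587 ± 0.125 (unadjusted p of the difference 0.0262, adjusted over all probe sets 0.858). The fitted peak of tim was at 15.7 h in LD and 17.0 h in DD. The 10 genes with the smallest p did not pass. The first was Obp99a, an odorant-binding protein gene, with a fitted peak at 15.3 h in LD and 20.2 h in DD (adjusted p 0.858). The second was the photoreceptor gene retinophilin (rtp), with amplitudes of 0.391 in LD and 0.178 in DD and peaks at 5.43 and 19.5 h. The others were CG32795, Hrd3, Edg78E, Sf3a1, gdrd, CG13324, pst and CaBP1. Simulated data held 200 changed probe sets and independent noise per array. There this test recovered 0% of rhythms that differed by 1 (log2, peak to trough) and 72% of those that differed by 2. Sizes between these were not simulated. With fewer changed probe sets the adjusted threshold is stricter, so these shares may be too high for the data.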

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

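The tests of body tissue, of clock time, of hybridization controls, of drift or trend and of the effect of leaving out ZT4 and CT12 were chosen after the results had been seen. The exchange of regime within clock times was added late, but before its own result was seen. A sample was singled out where its gap to the nearest other array of its day exceeded Dixon's critical value at the level of 1 in 20, which happened in 14 of 112 groups of 6 arrays, against 5.6 expected by chance.

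CT12 had the lowest interquartile range of its day (2.22 against 2.32 to 2.36) and the lowest median correlation with the other arrays (0.966 against 0.98 to 0.988). ZT4 had the highest difference between 3' and 5' control probe sets of its day (3.12 against 1.82 to 2.20) and the highest hybridization control signal (10.6 against 9.39 to 9.69). Antioxidant genes were lowest at ZT4 in LD (-0.308) and at CT12 in DD (-0.547). At CT12 the scores of photoreceptor transmitter handling (-0.201) and proteasome genes (-0.305) were also lowest. The array apart for per (6.1), dco (7.46) and cry (7.16) in DD was CT12, for Acp1 in DD CT24 (10.6), for Listericin in LD ZT24 (9.48), and for the ovary and eggshell score in LD ZT12 (0.234).

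The first pattern is that ZT4 and CT12 stood apart from the other 10 arrays. Body tissue in the sample does not explain both, since the body marker score of ZT4 was -0.308, below the median of -0.0678 of the other 10. Partial RNA degradation is a candidate explanation: the lower of the 2 control transcript differences, 3.12, lay above the highest of the other 10, 2.64. Time of day cannot account for it alone, as the arrays at the same clock times on the other day, CT4 and ZT12, had 2.64 and 1.86. Less labelled sample RNA is another: the hybridization control means of ZT4 and CT12 were 10.6 and 10.5, against at most 9.69 in the other 10, and these values do not part it from degradation.

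The second pattern is the variation of midgut, male reproductive tract and muscle transcripts, which would move together if pieces of body passed the sieves with the heads. Over 12 arrays, the midgut and male scores did so (r = 0.829, rho = 0.895; permutation p 0.00043 and 0.00028, adjusted 0.00258 and 0.00168 over 6 relations; r = 0.879 without the 2 arrays farthest out; 0.821 in LD and 0.935 in DD). Muscle did not clearly do so, with the smallest of the 3 correlations at 0.517 (permutation p 0.0861; rho = 0.545, p 0.0727; adjusted 0.172 and 0.188), and the male and muscle scores were at r = 0.532 (p 0.0745; rho = 0.51, p 0.0942), falling to 0.177 without CT12 and CT4, on which that relation rests. Ovary markers correlated with the midgut score at 0.91 in LD, where ZT12 stood apart, and at -0.225 in DD. Over 12 arrays r was 0.465 (permutation p 0.118) and rho 0.28 (p 0.378). Without the 2 farthest arrays, ZT12 and CT12, r was -0.0748, so body tissue as a whole stays open. The midgut score also followed clock time, with r = 0.893 between days over 6 clock times (exact permutation p 0.0153; rho = 0.771, exact p 0.103; 0.794 without the 2 farthest), so a daily rhythm and a daily difference in handling both may contribute. The male score too was low at 16 and 20 h of both days (-0.518 to -0.436). The permutation p-values over 12 arrays treat the arrays as interchangeable and ignore this shared clock time, so they may be too small.

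The third pattern is the 12 probe sets that differed between days, which ZT4 and CT12 do not carry, as the median size without them was 0.896 of its value and 8 of the 12 were among the 10 then called. A gradual effect of age or order was set against a step. The step from ZT24 to CT4, of single arrays, was 1.01 of the difference (median). With a steady trend fitted beside regime it was 1.19 over all 12 (median). It was 1.43 in the 10 probe sets left when CG34166 and Gnmt were set aside after their values were seen (median, 8 at an unadjusted p under 0.05). Standard errors were 3.19-fold over the 12, and 0 passed. The step was -0.0164 ± 0.223 in CG34166 and -0.377 ± 0.237 (SE) in Gnmt. In these 2 trend and step cannot be told apart. Without the cosine and sine they were 0.813 ± 0.225 and 0.849 ± 0.316, and from ZT24 to CT4 0.514 and 0.546. The 12 were called by a fit with 1 level per day, which favours steps over gradual change. CT4 also had a raised control transcript difference (2.64), and without it 1 of the 12 passed. These values therefore do not settle whether a gradual effect made the third pattern. Midgut or male reproductive tract tissue does not match it as the whole cause, since with these scores the sizes were 0.972 and 0.881 of their value, with standard errors 1.04-fold and 1.11-fold, and 11 and 10 probe sets passed, 10 and 8 of them among the 12. Muscle cannot be told apart from regime, as its score correlated with regime at 0.766, and with it the size was 0.805, the standard errors 1.58-fold and 0 passed. The mean of the 3 scores gave 0.877 and 0 passing (smallest limma adjusted p 0.0536). Its standard errors were 1.15-fold, with 7 in place of 8 residual degrees of freedom. The pooled markers gave 0.902 and 10, so muscle stays open. Darkness and any other change between the days, abrupt or gradual, stay open too.

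Other splits bear on the counts. In 4 of 100 splits of the arrays into 6 and 6, the real one included, as many probe sets differed as the real 12. These splits ignore clock time. The others among them gave 795, 235 and 166, and each put ZT4 and CT12, the 2 arrays that stood apart, on the same side. The highest joined them with the 4 arrays of 16 and 20 h. These 2 arrays may therefore raise such counts, which was not tested. With regime exchanged within clock times, 1 of 32 assignments, the real one, gave 12, and the highest other gave 0, so chance is excluded at 5% among these assignments, though not another difference between the days. Of 100 orders of the clock times, 3, the real one included, gave at least the 1 rhythmic probe set seen, and the highest other gave 18. That share is under 5%, but 100 drawn orders place it loosely, and 10000 random orders in the Fourier test called 0 (smallest adjusted p 0.279), so chance is not firmly excluded for this count. For core clock genes at an unadjusted p under 0.05, 1 of 100 orders, the real one, reached 7, and the highest other reached 6. Chance is thus excluded for them at 5% among these drawn orders only, with the highest other close to the real count. For the light test there are only 20 choices of clock times, too few for a share under 0.05, and the real value and the highest other were both 0. For rhythm differences all 32 assignments, the real one included, gave 0, and with a real count of 0 this says nothing about chance.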

How the results depend on the processing

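Alternatives that leave out ZT4 with CT12 (and CT4), weight arrays, add covariates, test lists at an unadjusted p or normalize lists again were chosen after the data were seen. The 5 core clock genes rhythmic over the list alone stayed between 4 and 7 under all alternatives but 1, the DD day only (3); leaving out single arrays gave 4 to 7. Of 28 settings at 0.05, the reported one included, tim and vri passed in 28, Usp8 in 27 and per in 25, and slmb in 26 of 27. Counts over all probe sets were less stable. The 1 rhythmic probe set became 0 with a variance trend, at a threshold of 0.01, with no regime term, in the LD day only, in the DD day only, by permutation of Fourier power (smallest adjusted p 0.279), and without ZT4 and CT12 or also CT4. It became 3 with a 12-h harmonic, 2 with the control transcript difference as a covariate, and 9 with array quality weights, among them tim, vri and Usp8. Leaving out single arrays gave 0 to 1. The 12 probe sets differing between days became 0 at a threshold of 0.01, 40 with array weights and 30 with the control transcript difference, and each of these last 2 held the original 12. They became 0 with the mean body score, with the muscle score, or with a steady trend over the hours fitted beside regime, also chosen after the data were seen. They numbered 11 with clock time as a block (8 shared), 11 with the midgut score, 10 with the male reproductive tract score and 10 with the body markers pooled. Leaving out single arrays gave 1 to 22. The light and rhythm difference counts stayed at 0 in limma under every alternative run, with 224 to 2329 and 194 to 1520 probe sets at an unadjusted p under 0.05. Of 8 lists that shifted between days, 2 held with an estimated correlation, and 7 passed with centred arrays and 9 after a further quantile normalization. Without ZT4 and CT12, with the preset correlation, 8 passed, of which 6 were among the first 8. Testis and accessory gland (adjusted p 0.206) and antioxidant genes (0.314) lost the call. Xenobiotic detoxification (0.00879) and glial markers (0.0062) gained it. Of 2 lists that shifted with light, 0 held with an estimated correlation. Without ZT4 and CT12 5 passed with the preset one, the testis list with the opposite sign. Rhythmicity of lists went from 0 to 2 lists at an unadjusted p. Of the named genes that had passed, Culd and the 11 that differed between days, none changed direction, the steady trend fit aside. In that fit the step was 0.035 ± 0.476 (log2, SE) for CG34166 and 0.63 ± 0.396 for Gnmt. Both are opposite in sign to the differences between days, -2.13 and -1.67. The other named genes were not checked for a change of direction. For the 11 genes that differed between days, 119 of 319 values under alternatives lost the call. Except where an alternative has a stricter threshold or fewer arrays, the cause was not tested. The deposited values hold no measure of signal over background, so its limit on low probe sets was not analysed here.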

Other observations

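The test of the cuticle gene family was chosen after the result had been seen; that of muscle and mitochondria was written before its result.

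Beyond the genes named by rule, 58 measured genes of the Cpr family, which encode cuticle proteins with a chitin-binding domain, had a mean DD minus LD difference of 0.126 (log2), and 41 were positive. Cpr97Eb was 6.46 ± 0.367 (SD, n = 6) in DD and 5.55 ± 0.0918 (n = 6) in LD, and Cpr100A was 7.90 ± 0.441 and 6.99 ± 0.219. Both were higher in DD at all 6 clock times. Adjusted over the family alone 5 rose and 0 fell, and over all probe sets 0 passed. The family was picked because Acp1 and Gasp had been seen to rise. The hypothesis that its members rise together in DD did not pass: the camera p was 5.63e-07 with the preset correlation but 0.0572 with the estimated one.

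Mitochondrial respiration genes and muscle markers were both higher in DD. The muscle score was 0.294 ± 0.274 (SD, n = 6) in DD and -0.294 ± 0.267 (n = 6) in LD. With that score as a covariate the median difference of the mitochondrial list fell from 0.196 to 0.086, a ratio of 0.44, with 52 of 73 members positive (camera p 0.000246 with the preset correlation and 0.0702 with the estimated one). More muscle tissue in the DD samples could be one source of the shift. The markers in the muscle score were not alike, however. At 16 and 20 h fln was 3.12 and 3.22 in LD and 3.06 and 3.13 in DD. Act88F was 4.09 and 3.82 against 4.21 and 4.78, and Mlc1 8.39 and 8.39 against 9.46 and 9.79. The mitochondrial score at these hours was -0.146 and -0.0963 in LD and 0.118 and 0.116 in DD. Heads hold muscle too, so the muscle score does not part thorax from head muscle. The score correlated with regime at 0.766, so part of the drop could come from the overlap of the 2 terms. For comparison, the sizes of the 12 probe sets called between days stayed at 0.805 of theirs under the same covariate.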
